A study of Mus musculus with 8 samples.

How the data were processed

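Gene expression was measured in adipose tissue of obese mice on a high-fat diet, all on a C57Bl6 background, with Illumina bead arrays, 1 sample per array. Per the labels, the mice had fasted for 5 h, the tissue was snap-frozen, RNA was purified on columns with a DNase step, and biotinylated cRNA was made from it. The groups are wild type (WT, n = 2, age 24 weeks), IL6 knock-out (IL6_KO, n = 3, 25 weeks) and sgp130Fc transgenic (n = 3, 26 weeks). Age differs between the groups and not within them, so an effect of age is confounded with genotype. The fat depot, the sex, the time of collection and the chips were not used here. The labels number the replicates without saying that each comes from a separate animal, so the p-values measure the spread between these samples, part of which may be technical.

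The deposited probe intensity is on a linear scale, neither background-subtracted nor normalized between arrays, for 25697 probes. Beside each intensity the authors gave a detection p-value against the negative control probes of that array, per the file headers, and these p-values fell with the intensity of their own array (rank correlation -0.966 or closer to the limit). The authors also deposited normalized log2 values with the same column median of 5.04 on each array, and the labels name GenomeStudio and limma without versions. Background correction and quantile normalization of the deposited intensities with the neqc function of limma gave values within 0.0548 of those log2 values, with a median difference of 0.000277.

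The intensities were normalized anew with neqc in limma 3.58.1 (R 4.3.3), which inferred the negative controls from the detection p-values and added an offset of 16. Probes with a detection p under 0.05 on at least 2 arrays were tested, which left 14141 probes for 9803 genes, 10865 of the probes being detected on all 8 arrays. Probe names came from the array annotation and were checked against RefSeq genes of GRCm38.p6: 23978 probes had 1 symbol, 1719 had none given, 0 had several, and 23962 gene identifiers were matched with 0 symbols changed.

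A linear model with the 3 groups as its terms was fitted to all 8 arrays with lmFit and eBayes of limma, and the comparisons IL6_KO minus WT, sgp130Fc minus WT and sgp130Fc minus IL6_KO were tested on both sides. P-values were adjusted by Benjamini-Hochberg over all probes within each comparison, with a threshold of 0.05. The moderated test had 8.98 degrees of freedom, 3.98 of them from the prior. Levels are normalized log2 intensities, given as mean ± SD. Where the dimmer group was not detected on any of its arrays, the fold is a lower bound computed against the detection limit of those arrays and is written as "at least". Where a gene had several tested probes, the brightest represents it in the lists and the fixed set, and for genes taken from the extremes it is the passing probe with the largest change.

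There were 44 gene lists with 893 entries for cell types, pathways and tissues that a fat sample could hold, of which 4 entries matched no gene. Each list with at least 3 measured members was tested with camera of limma with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over all lists and comparisons. The same lists were tested with a correlation estimated from the data and with fry, a directional rotation test of limma. Members that passed after adjustment over the list alone were counted beside those passing over all probes. Near-identical genes (the beta globins, the Ccl21 copies, Gbp2b and its relatives) cannot be assigned to 1 copy with certainty.

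The genes named were chosen by a rule. It takes Il6, Il6ra and Il6st. From each comparison it takes the 10 genes with the highest and the 10 with the lowest log2 difference among those passing whose group ranges do not overlap, filled up to 20 by the smallest p. It takes the 4 members of smallest p in the direction of each called list, and the fixed set Adgre1, Cd68, Itgax, Ccl2, Tnf, Socs3, Saa3, Lep, Adipoq, Slc2a4 and Fasn. Cd68 had no tested probe and is not analysed here. The groups, the comparisons, the lists, this rule and the alternatives below were set before the data were examined.

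The alternatives were quantile normalization without background correction, the deposited log2 values, an offset of 50, scaling to the 75th percentile, no detection filter, detection on all 8 arrays, an intensity trend in eBayes, array weights, a fit of the compared groups alone, the replicate number as a block, leaving out each array, genes in place of probes, and an added minimum log2 difference of 1. The lists were also run with the mean of all probes of a gene. Because both comparisons with WT share the same 2 WT arrays, the correlation and covariance of their log2 differences were set against 100 simulations without any difference between groups. Calls shared by both were set against independent lists only. The model was tested on simulated data of the same size and spread. It found 58.2% of the probes given a log2 change of 1 in either comparison with WT and 80.6% in sgp130Fc minus IL6_KO, at least 98.5% of those given a change of 2, and called 0 probes where none had been changed. Between 4.47% and 6.52% of the calls were false. A list shifted by 0.5 was recovered as the 1 called list in each comparison. The simulated probes varied independently, so this does not show how the list test behaves when genes of a list vary together.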

Results

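Adipose expression was profiled in 8 samples from obese, high-fat-fed mice: 2 WT, 3 IL6_KO and 3 sgp130Fc transgenic. IL-6 is a cytokine released by fat, muscle and immune cells. sgp130Fc is a soluble gp130 receptor fused to an antibody Fc part. It captures IL-6 bound to its soluble receptor, so that it blocks IL-6 trans-signalling and leaves signalling through the membrane receptor. The comparisons ask how loss of all IL-6, or of trans-signalling alone, alters obese fat. Median intensity per array before normalization lay between 109.1 and 145, and 12499 to 13378 probes (48.6% to 52.1%) were above background. The lowest medians were those of sgp130Fc replicates 3 (109.1) and 2 (119.7), and the other arrays had 131.5 or more. The number of arrays limits the precision: the median standard error of a log2 difference was 0.21 against WT and 0.19 between the other groups. IL6_KO replicate 2 stood apart. Its mean correlation across probes with the other arrays was 0.944 (0.964 to 0.973 for the rest; probes are not independent replicates). It scored 62.6 on the first principal component, which held 44.6% of the variance, and the other arrays -27.3 to 23.7.

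Il6 itself (probe ILMN_1243601) lay near background in every group and was detected on 2 arrays, both IL6_KO. Its level was 4.44 ± 0.05 in WT (SD, n = 2) and 5.13 ± 0.05 in IL6_KO (n = 3), at least 1.06-fold higher, which did not pass (adjusted p = 0.0922). Where this probe lies relative to the deleted part of the gene is not known here, so it does not check the genotype. Il6st, which encodes the signal-transducing receptor gp130, lay at 9.79 ± 0.04 in WT, 9.71 ± 0.03 in IL6_KO and 9.73 ± 0.15 in sgp130Fc. Il6ra, the IL-6-binding receptor chain, lay at 5.57 ± 0.24, 5.82 ± 0.33 and 5.58 ± 0.52. Neither gene passed in any comparison. The transgene was not analysed here.

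In IL6_KO fat, 31 named genes differed from WT, 10 higher and 21 lower, with macrophage products among the higher and red blood cell genes among the lower ones. Mmp12, a macrophage elastase, rose from 10.89 ± 0.11 in WT (n = 2) to 13.14 ± 0.54 in IL6_KO (n = 3), 4.77-fold (adjusted p = 0.0467). Ctsk, the collagen-degrading cathepsin K, rose 3.68-fold from 11.12 ± 0.48, and Il1rn, the IL-1 receptor antagonist, rose from 7.46 ± 0.20 to 9.79 ± 0.66. Prkag2 (ILMN_3161626), a regulatory subunit of AMP-activated protein kinase, lay at 8.61 ± 0.23 in WT and was not above background on any IL6_KO array, so at least 12.1-fold lower (adjusted p = 7.16e-05). Gdpd3, a lysophospholipase D, fell 13.1-fold from 10.67 ± 0.23 to 6.97 ± 0.15 (adjusted p = 8.15e-05).

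Other higher genes were Cd300ld, a myeloid receptor (log2 difference 3.92 ± 0.59, SE; above background on 1 of 2 WT arrays), and Cyba, a subunit of the phagocyte NADPH oxidase (1.16). Also higher were the protease gene Prss46 (1.95), Evi2 (1.59), the phospholipid transporter Abcb4 (1.46), Kansl1l (1.38, above background on 1 of 2 WT arrays) and the kininogen gene Kng2 (1.24). Among the lower genes, the interferon-inducible GTPase Gbp2b was at least 19.6-fold lower, with levels of 10.48 and 8.15 on the 2 WT arrays. Fam107a was at least 3.40-fold lower (adjusted p = 0.00203). Napepld, which makes N-acylethanolamines, fell 6.42-fold (adjusted p = 0.000364), the potassium channel Kcnh2 5.97-fold (above background on 1 of 3 IL6_KO arrays), the endothelial nitric oxide synthase Nos3 5.67-fold and Depp1 5.08-fold. The brightest probe of Napepld fell by 1.91 (adjusted p = 0.0199), and that of Nos3 differed by -2.46 and did not pass (adjusted p = 0.0658). Retn, the adipokine resistin, fell 3.85-fold from 7.04 ± 0.34 to 5.10 ± 0.52, above background on 1 of 3 IL6_KO arrays.

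Of the 31 genes, 5 lie within 200 protein-coding gene places of Il6 on chromosome 5 of GRCm38.p6: Abcb4, Napepld, Kcnh2, Nos3 and Prkag2. That is 2.81% of 178 tested genes near Il6 against 0.271% of 9587 elsewhere. The odds ratio was 10.6 (95% interval 3.15 to 28.5, one-sided Fisher's exact p = 0.000220). All 5 lie on the same side of Il6, and in sgp130Fc minus WT 0 of the 178 were called. In sgp130Fc minus IL6_KO 6 of the 178 were called, the same 5 and the transcription cofactor gene Ldb2 on the other side (0.98, adjusted p = 0.0267). That is against 150 of 9587 elsewhere (odds ratio 2.19, 95% interval 0.782 to 4.99, one-sided Fisher's exact p = 0.0656). Of the 157 named genes called in that comparison, 156 had a place in the gene order and were counted.

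**Figure D1:**
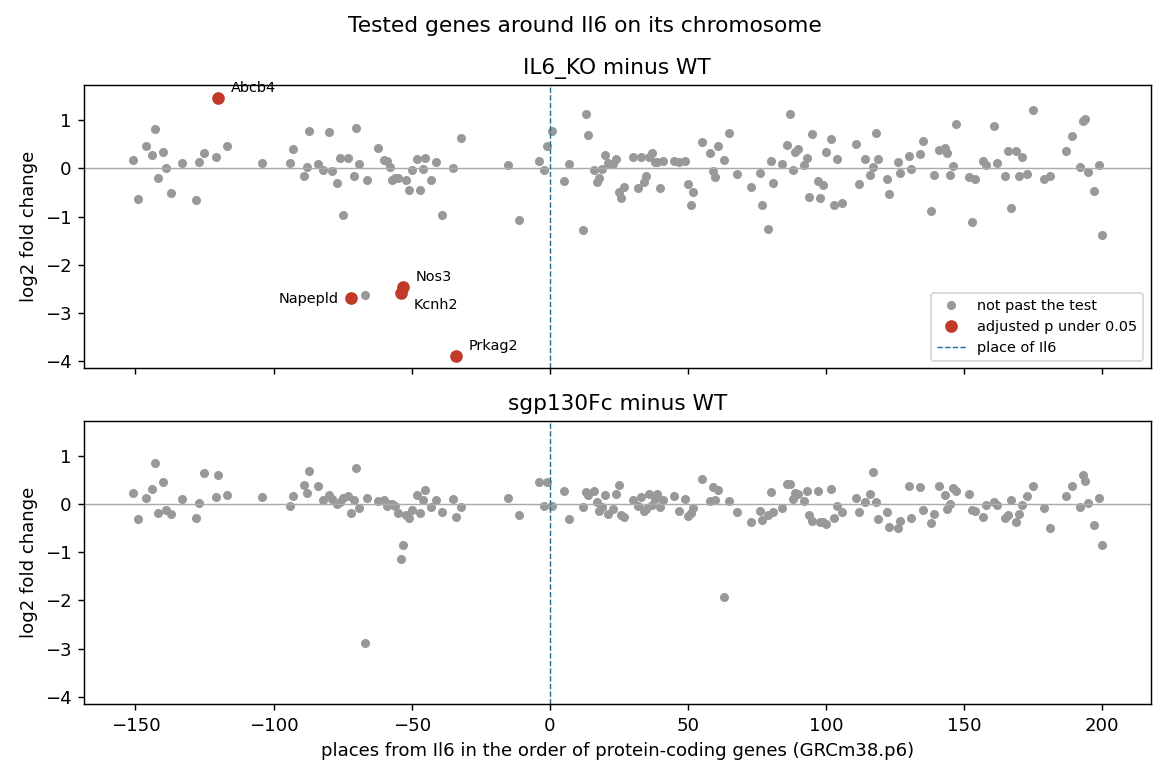
Log2 difference from WT of the tested genes around Il6 on chromosome 5, by gene place from Il6, for IL6_KO and for sgp130Fc; coloured points passed the test. The 5 genes that passed in IL6_KO all lie before Il6 in the gene order, and 0 passed in sgp130Fc.

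Pan-macrophage and lipid-associated macrophage genes lay higher in IL6_KO than in WT as groups. Of 20 measured pan-macrophage genes, 0 passed over all probes, 14 were higher and 0 lower when adjusted over the list alone, and 19 had a positive difference (median log2 difference 0.76, camera adjusted p = 6.24e-09). This list had adjusted p = 0.479 with an estimated correlation. Adgre1, which encodes the macrophage marker F4/80, lay at 12.16 ± 0.17 in IL6_KO and 11.25 ± 0.03 in WT (adjusted p = 0.0881). Tyrobp, a myeloid signalling adaptor, differed by 1.32 (adjusted p = 0.0693). Among 15 genes of lipid-associated macrophages, Mmp12 and Ctsk rose and 13 did not pass, and 11 were higher when adjusted over the list alone (median 0.88, adjusted p = 1.41e-07). They had adjusted p = 0.479 with an estimated correlation. Trem2, a lipid-sensing receptor of these cells, differed by 1.37 (adjusted p = 0.0875) and Dcstamp, a cell-fusion protein, by 2.11 (adjusted p = 0.0777). Genes of resident macrophages were not called: of 17 measured, 0 passed, 9 had a negative difference, and 1 was higher and 3 lower when adjusted over the list alone (median -0.22, adjusted p = 0.268).

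Of 21 phagosome and lysosome genes 0 passed and 10 were higher when adjusted over the list alone (median 0.55, adjusted p = 8.30e-06). The list had adjusted p = 0.615 with an estimated correlation, and the lysosomal lipase Lipa differed by 1.43. Of 23 chemokine and recruitment genes 0 passed and 5 were higher when adjusted over the list alone (median 0.40, or 0.39 with dim genes at their bound, adjusted p = 0.00152). Here too adjusted p = 0.479 with an estimated correlation, and the macrophage chemokines Ccl3 and Ccl4 differed by 1.53 and 1.34. Itgax, which encodes CD11c, differed by 0.88 (adjusted p = 0.187). The monocyte attractant Ccl2 differed by 0.80 (adjusted p = 0.262) and Tnf by 0.28 (adjusted p = 0.506), or by 1.24 and 0.09 without IL6_KO replicate 2.

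Genes of fat cells and of fat synthesis lay lower in IL6_KO. Of 20 adipocyte markers Retn fell, 19 did not pass, and 0 were higher and 4 lower when adjusted over the list alone (median -1.05, adjusted p = 8.73e-06). Adipocyte markers had adjusted p = 0.615 with an estimated correlation. The insulin-responsive glucose transporter Slc2a4 differed by -1.54 (adjusted p = 0.109), Adipoq, which encodes adiponectin, by -0.65 (adjusted p = 0.313) and Lep, which encodes leptin, by -0.57 (adjusted p = 0.321). Without IL6_KO replicate 2 Adipoq differed by -0.25 and Lep by -0.21. All 20 lipogenesis genes had a negative difference, 0 passed, and 4 were lower when adjusted over the list alone (median -1.01, adjusted p = 1.47e-06). Lipogenesis genes had adjusted p = 0.615 with an estimated correlation. Fatty acid synthase, Fasn, differed by -1.71 (adjusted p = 0.0736) and its regulator Srebf1 by -1.01 (adjusted p = 0.0881).

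Lipolysis genes had a median of -0.77 over 13 members (adjusted p = 0.00183; adjusted p = 0.653 with an estimated correlation). For 20 fatty acid oxidation genes it was -0.44 (adjusted p = 0.00183; adjusted p = 0.661 with an estimated correlation). In both lists 0 passed, also adjusted over the list alone. Of 13 adipokines Retn fell, and it was the 1 lower when adjusted over the list alone (median -0.70, adjusted p = 0.00515). Adipokines had adjusted p = 0.615 with an estimated correlation. The adipocyte and lipogenesis medians were most negative on IL6_KO replicate 2. Without that array the differences were -0.49 for adipocyte markers, -0.63 for lipogenesis, -0.37 for lipolysis, -0.20 for fatty acid oxidation and -0.25 for adipokines, all still called.

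Vessel and blood genes lay lower as well. Of 16 endothelial genes 0 passed, 15 had a negative difference and 14 were lower when adjusted over the list alone (median -0.74, adjusted p = 1.61e-07). Endothelial genes had adjusted p = 0.479 with an estimated correlation. Gpihbp1, which anchors lipoprotein lipase on capillaries, differed by -1.25 and the receptor gene Tie1 by -1.13. Of 9 smooth muscle genes 0 passed and 6 were lower when adjusted over the list alone (median -1.23, adjusted p = 9.44e-05). Smooth muscle genes had adjusted p = 0.479 with an estimated correlation, and their myosin Myh11 differed by -1.40 (adjusted p = 0.0529). Of 5 erythroid genes 3 fell over all probes and 5 were lower when adjusted over the list alone (median -2.52, adjusted p = 1.98e-06). Erythroid genes had adjusted p = 0.479 with an estimated correlation. Alas2, the erythroid enzyme of haem synthesis, fell 15.4-fold, with levels of 11.48 and 9.77 on the 2 WT arrays. The beta globin gene Hbb-bt fell 5.73-fold, from 12.03 ± 0.36 to 9.51 ± 0.57.

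The medians of connective tissue and chaperone genes lay higher, by less and with members on both sides. A negative difference was seen in 11 of 31 extracellular matrix genes, 3 of 15 preadipocyte and fibroblast genes and 6 of 18 endoplasmic reticulum stress genes. Extracellular matrix genes had a median of 0.25 over 31 (adjusted p = 0.0295; adjusted p = 0.615 with an estimated correlation), with 0 passing and 4 higher when adjusted over the list alone. The call was lost without WT replicate 1 (0.24), with scaling to the 75th percentile and with detection on all arrays, and the median was 0.37 without WT replicate 2. Preadipocyte and fibroblast genes had 0.19 over 15 (adjusted p = 0.0334; adjusted p = 0.479 with an estimated correlation), with 0 passing, also adjusted over the list alone. That call was lost without WT replicate 1 (0.20) or IL6_KO replicate 3 (0.31), with array weights and with the replicate block. Genes of endoplasmic reticulum stress had 0.31 over 18 (adjusted p = 0.0437; adjusted p = 0.633 with an estimated correlation), with 0 passing and 1 higher when adjusted over the list alone. They lost the call without WT replicate 1 (0.12), IL6_KO replicate 1 (0.22) or 3 (0.31) and with detection on all arrays, and their median was 0.17 without background correction and 0.13 with no detection filter. The metalloprotease Mmp14 differed by 1.27 (adjusted p = 0.117), the receptor Pdgfra of fibroblasts by 0.62 (adjusted p = 0.188) and the stress-induced Atf3 by 1.43 (adjusted p = 0.0644).

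Genes that IL-6 is known to induce through STAT3 were not called: of 24 measured, 0 passed, also adjusted over the list alone, and 14 had a positive difference (median 0.18, or 0.09 with dim genes at their bound, adjusted p = 0.601). Without IL6_KO replicate 2 their median was 0.06. Socs3, the feedback inhibitor that IL-6 induces, lay at 8.36 ± 0.18 in IL6_KO and 7.88 ± 0.30 in WT (adjusted p = 0.261). Saa3, an acute-phase gene of fat, differed by 0.19 (adjusted p = 0.884), and by -0.76 and 1.14 without WT replicates 1 and 2. The 16 genes of the IL-6 pathway had a median of -0.01 and a mean of 0.06 (adjusted p = 0.675). Of 44 lists 21 were called, 11 higher and 10 lower, and 0 with an estimated correlation or with fry. The 35 probes passing (10 higher and 25 lower, with 2912 at an unadjusted p under 0.05) became 8 and 778 without IL6_KO replicates 1 and 3. They became 7, 6 and 11 without sgp130Fc replicates 1, 2 and 3. Of the 20 genes named from the extremes, Prkag2, Gdpd3, Napepld and Fam107a passed with each array left out, and the other 16 did not, nor did Retn, at adjusted p up to 0.186.

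**Figure D2:**
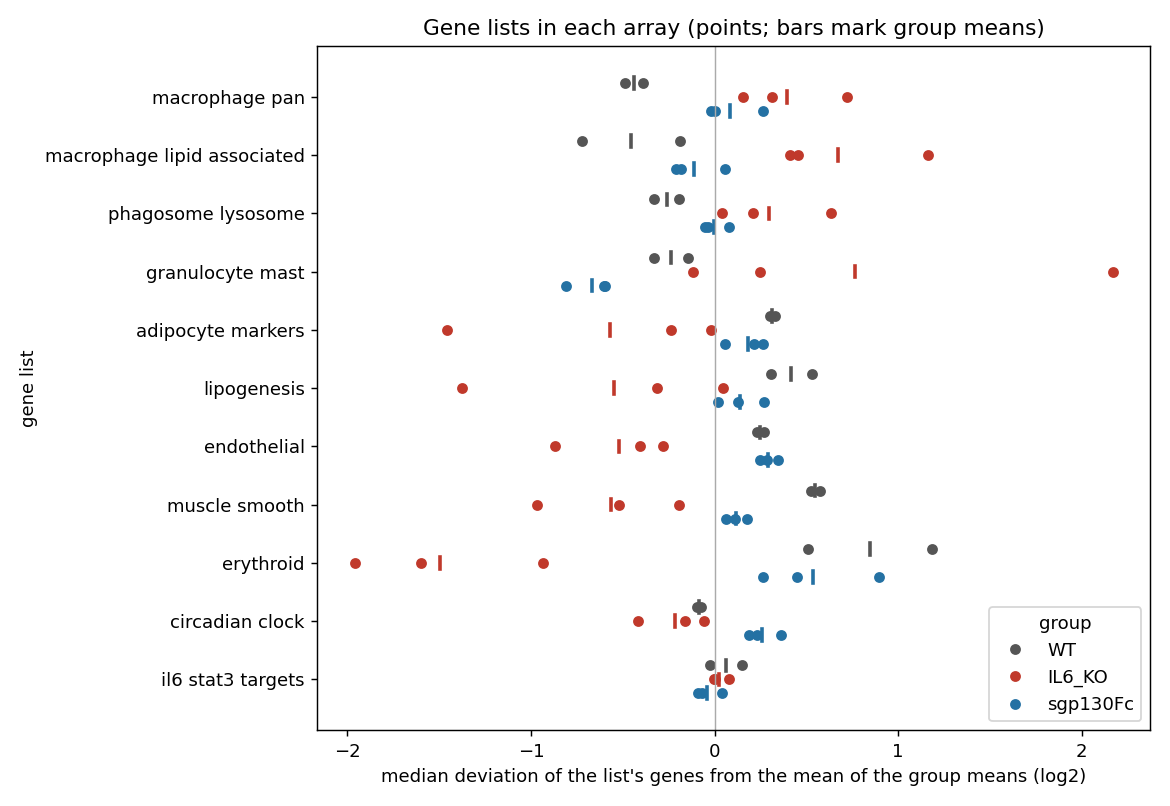
Median centred log2 level of 11 gene lists on each of the 8 arrays, with a bar at each group mean. Pan-macrophage genes were at -0.49 and -0.39 on the WT arrays and at 0.16 to 0.72 on the IL6_KO arrays, and adipocyte markers at -1.46 on IL6_KO replicate 2.

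In sgp130Fc fat, 12 named genes differed from WT, 6 higher and 6 lower. Chil1, a chitinase-like protein of macrophages and neutrophils, was not above background in WT and lay at 8.22 ± 0.68 in sgp130Fc (n = 3), at least 9.05-fold higher (adjusted p = 0.00624). Itgad, the integrin subunit CD11d of macrophages, rose from 6.24 ± 1.03 (n = 2) to 9.75 ± 0.23 (adjusted p = 0.0413). On the IL6_KO arrays Itgad lay at 7.96 to 9.20, also above both WT arrays. The core clock gene Per2 rose 4.22-fold, from 8.16 ± 0.14 to 10.24 ± 0.14 (adjusted p = 0.0134). Gdpd3 fell 14.6-fold to 6.81 ± 0.20 (adjusted p = 5.63e-05), and the probe ILMN_1217331 of Mcm6, a subunit of the DNA replication helicase, fell from 9.20 ± 0.07 to background on every sgp130Fc array, at least 17.7-fold lower (adjusted p = 2e-05).

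Of the other 2 Mcm6 probes 1 differed the same way and 0 passed. Further higher genes were Ctse, the endosomal protease cathepsin E (at least 4.46-fold higher, adjusted p = 0.00904), the IL-13 decoy receptor Il13ra2 (log2 difference 2.12, adjusted p = 0.0413) and Kansl1l (1.72, adjusted p = 0.0134). Gbp2b (-4.66, adjusted p = 0.0221) and the scavenger receptor Cd163l1 (-2.45, adjusted p = 0.0413) were lower, above background on 1 and 2 of 3 sgp130Fc arrays. So were Timmdc1, an assembly factor of respiratory complex I (-1.78, adjusted p = 0.0214), and the MAP kinase phosphatase Dusp4 (-1.28, adjusted p = 0.036). Short of the threshold, the lymphoid chemokine Ccl21a differed by -4.58 (adjusted p = 0.0742) and the RANK receptor Tnfrsf11a by 1.74 (adjusted p = 0.0742). So did the clock repressor Ciart, by 1.19 (adjusted p = 0.0585), above background on 1 of 2 WT arrays. On the IL6_KO arrays Cd163l1 lay at 5.95 to 6.21 and Ccl21a at 6.35 to 8.11. Both were lower there than on the WT arrays (8.24 and 7.42 for Cd163l1, 11.46 and 9.95 for Ccl21a). Il13ra2 lay at 5.05 to 5.96 in IL6_KO, near its WT levels of 5.13 and 5.70.

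Pan-macrophage genes lay higher than in WT here too. Of 20 measured, 0 passed over all probes, 19 had a positive difference, and 8 were higher and 0 lower when adjusted over the list alone (median 0.56, camera adjusted p = 6.24e-09). In sgp130Fc they had adjusted p = 0.479 with an estimated correlation. The Fc receptor Fcgr1 differed by 1.04 (adjusted p = 0.181) and Adgre1, at 11.96 ± 0.29, by 0.71 (adjusted p = 0.416). Of 10 complement genes 9 had a positive difference and 0 passed, also adjusted over the list alone (median 0.51, or 0.38 with dim genes at their bound, adjusted p = 0.00208). Complement genes had adjusted p = 0.479 with an estimated correlation, and the C1q chain C1qc differed by 0.67.

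Of 16 clock genes Per2 rose and 15 did not pass, and 5 were higher and 2 lower when adjusted over the list alone (median 0.20, adjusted p = 0.0407). Clock genes had adjusted p = 0.479 with an estimated correlation. Their call was lost without WT replicate 2 (0.25) and without sgp130Fc replicate 1 (0.20) or 2 (0.13), and their median was 0.31 without WT replicate 1. It was also lost with no detection filter and with detection on all arrays. Genes of liver proteins lay lower, with 9 of 9 negative and 0 passing, also adjusted over the list alone (median -1.86, adjusted p = 2.92e-05). Liver genes had adjusted p = 0.615 with an estimated correlation. The apolipoprotein Apoa2 differed by -3.15 and the transthyretin gene Ttr by -2.70. These genes were bright on WT replicate 1 and IL6_KO replicate 3, and without WT replicate 1 the call was lost (-1.11).

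Removing WT replicate 1 ended the calls of 6 further lists in this comparison. The phagosome and lysosome list had a median of 0.30 over 21 genes (adjusted p = 0.000671; adjusted p = 0.615 with an estimated correlation), and 0.17 without that array. Extracellular matrix genes had 0.22 over 31 (adjusted p = 0.00707; adjusted p = 0.615 with an estimated correlation), and 0.11 without it. T and NK cell genes had -0.29 over 17 (adjusted p = 0.0108; adjusted p = 0.689 with an estimated correlation), and 0.04 without it. Cell cycle genes had 0.28 over 19 (adjusted p = 0.0155; adjusted p = 0.723 with an estimated correlation), and -0.02 without it. Lipid-associated macrophage genes had 0.33 over 15 (adjusted p = 0.0295; adjusted p = 0.670 with an estimated correlation), and 0.10 without it. Genes of endoplasmic reticulum stress had 0.20 over 18 (adjusted p = 0.0295; adjusted p = 0.615 with an estimated correlation), and 0.12 without it. In these 6 lists 0 members passed over all probes, and 2 extracellular matrix genes and 0 of the others did so adjusted over the list alone. Among their members the glycoprotein gene Thbs2 differed by 1.01, the T cell receptor component Cd3g by -1.68 (above background on 2 of 3 sgp130Fc arrays) and the chaperone Hspa5 by 0.99. T and NK cell genes had a median of -0.90 without WT replicate 2 and -0.69 without sgp130Fc replicate 3, and lost the call without sgp130Fc replicate 1 (-0.17). Without WT replicate 2 the medians were 0.58 for cell cycle, 0.53 for lipid-associated macrophage and 0.33 for endoplasmic reticulum stress genes. The last list lost its call without sgp130Fc replicate 2 (0.19), and the lipid-associated list without sgp130Fc replicate 3 (0.31). Scaling to the 75th percentile ended the calls of these 2 lists, no detection filter those of the endoplasmic reticulum stress and the T and NK cell genes, detection on all arrays that of the T and NK cell genes, and the mean of all probes that of the cell cycle genes.

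Smooth muscle genes lay lower in sgp130Fc too, with 8 of 9 negative, 0 passing and 1 lower when adjusted over the list alone (median -0.27, adjusted p = 0.0458; adjusted p = 0.615 with an estimated correlation). The call was lost without WT replicate 2 (-0.26) or sgp130Fc replicate 1 (-0.15), with no detection filter and with detection on all arrays. The smooth muscle actin gene Actg2 differed by -1.32 (adjusted p = 0.330).

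Several lists called in IL6_KO were not called in sgp130Fc minus WT: adipocyte markers (median -0.18, adjusted p = 0.183), lipogenesis genes (-0.20, adjusted p = 0.105) and endothelial genes (-0.01, mean 0.01, adjusted p = 0.697). STAT3 targets of IL-6 (-0.10, adjusted p = 0.498) and the IL-6 pathway (-0.05, adjusted p = 0.255) were not called either. Socs3 lay at 6.98 ± 0.29 in sgp130Fc, a log2 difference of -0.90 from WT (adjusted p = 0.332). Ccl2 differed by -0.57, Tnf by -0.49 (above background on 1 of 3 sgp130Fc arrays), Itgax by -0.23 and Saa3 by 1.36, and none of them passed. Without WT replicate 2 Ccl2 differed by -0.35, Itgax by 0.06 and Saa3 by 2.31, and without WT replicate 1 Itgax by -0.52 and Saa3 by 0.41. Fasn differed by -0.61, Slc2a4 by -0.65, Adipoq by -0.22 and Lep by -0.07, again without passing. Of 44 lists 11 were called, 8 higher and 3 lower, and 0 with an estimated correlation or with fry. The 13 probes passing (7 higher, 6 lower; 1164 at an unadjusted p under 0.05) became 8 and 21 without IL6_KO replicates 1 and 2, and 8, 3 and 3 without sgp130Fc replicates 1, 2 and 3. Mcm6 and Gdpd3 passed with each array left out, and the other 10 genes did not, at adjusted p up to 0.210.

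The direct comparison of sgp130Fc with IL6_KO asks where loss of trans-signalling alone differs from loss of all IL-6. Here 157 named genes differed, 102 higher and 55 lower in sgp130Fc (n = 3 in each group). Ddit4, an inhibitor of mTOR signalling, lay at 11.02 ± 0.12 in sgp130Fc and 8.08 ± 0.31 in IL6_KO, 7.68-fold higher (adjusted p = 0.000238). Depp1, a FOXO target, was 11.8-fold higher (10.70 ± 0.23 against 7.15 ± 0.38), Per2 6.55-fold higher and Pdk4, a kinase that restrains glucose oxidation, 5.9-fold higher. Among mast cell genes, the chymase Cma1 lay at 6.10 ± 0.69 in sgp130Fc and 9.16 ± 0.84 in IL6_KO, 8.3-fold lower (adjusted p = 0.0177).

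Prkag2 was at least 10.1-fold higher in sgp130Fc than in IL6_KO (adjusted p = 2.46e-05) and Napepld 5.65-fold higher (adjusted p = 0.000238; 1.55 for its brightest probe). Chil1 was at least 9.21-fold higher (adjusted p = 0.00157) and Ctse at least 4.54-fold (adjusted p = 0.000862). Cd163, the haemoglobin scavenger receptor of resident macrophages, lay at 10.11 ± 0.24 against 7.32 ± 0.78 (adjusted p = 0.011). Mcm6 was at least 24.4-fold lower (adjusted p = 3.19e-06), with the other 2 probes lower and 1 of them passing. Also lower were Apoa2 (log2 difference -4.51, adjusted p = 0.034), Dcstamp (-2.42, adjusted p = 0.0243), Abhd1 (at least 4.52-fold, adjusted p = 0.0243; -2.22 for its brightest probe, adjusted p = 0.0114) and the coagulation factor gene F10 (-2.28, adjusted p = 0.0438).

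Of 16 clock genes 3 rose and 2 fell, and 9 were higher and 3 lower when adjusted over the list alone (median 0.71, camera adjusted p = 0.00631). The clock list had adjusted p = 0.479 with an estimated correlation. Per1 rose from 8.19 ± 0.15 in IL6_KO to 10.24 ± 0.08 (adjusted p = 0.00299), next to Per2 and Ciart (0.87, adjusted p = 0.034). Arntl, the activator that these repress, fell by 1.49 (adjusted p = 0.023) and Bhlhe40, another clock repressor, fell by 1.17 (adjusted p = 0.0375).

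Socs3 fell from 8.36 ± 0.18 in IL6_KO to 6.98 ± 0.29 in sgp130Fc, 2.61-fold (adjusted p = 0.0174), and did not pass without IL6_KO replicate 1 (-1.46), sgp130Fc replicate 1 (-1.25) or sgp130Fc replicate 3 (-1.37). Of the 24 STAT3 targets of IL-6 it fell with Bcl3 (-0.83, adjusted p = 0.0371), while Lcn2, the iron-binding lipocalin, rose from 7.63 ± 0.44 to 9.89 ± 0.23 (adjusted p = 0.037). The list was not called (median -0.12, adjusted p = 0.404), with 2 higher and 7 lower when adjusted over the list alone. The 16 IL-6 pathway genes had a median of -0.11, or -0.07 with dim genes at their bound (adjusted p = 0.136), with Socs3 the 1 member passing.

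**Figure D3:**
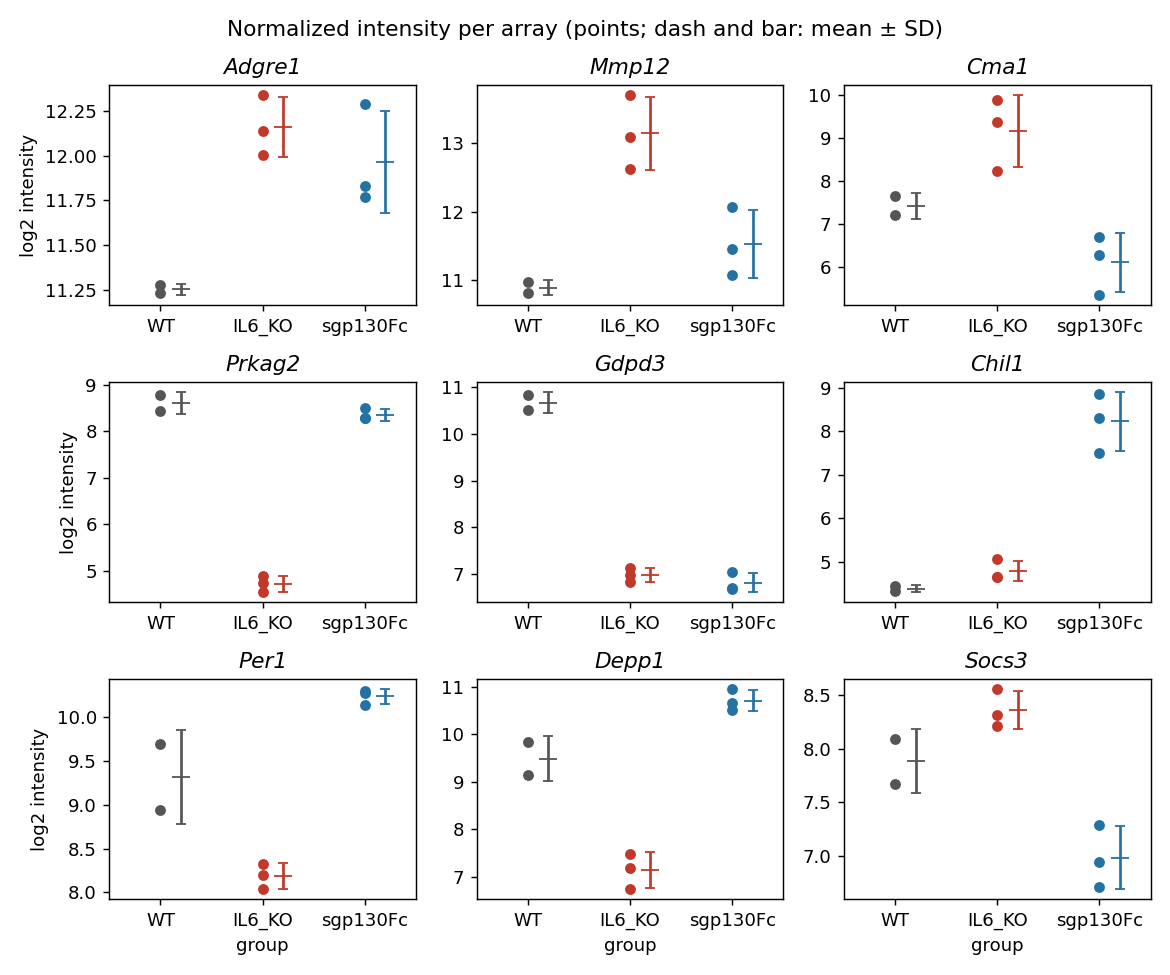
Normalized log2 intensity of 9 genes on each array, with the mean ± SD of each group. Prkag2 lay at 4.73 ± 0.17 in IL6_KO and 8.35 ± 0.12 in sgp130Fc, Gdpd3 was low in both altered genotypes, and Per1, Depp1 and Socs3 differed between them.

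Of 13 mast cell and granulocyte genes 4 fell and 9 did not pass, and 6 were lower when adjusted over the list alone (median -1.50, or -1.47 with dim genes at their bound, adjusted p = 1.09e-05). Mast cell genes had adjusted p = 0.615 with an estimated correlation. Beside Cma1, the chymase Mcpt4 (-3.38, adjusted p = 0.0266; above background on 2 of 3 sgp130Fc arrays), the carboxypeptidase Cpa3 (7.19-fold lower, adjusted p = 0.0267) and the tryptase Tpsb2 (-2.28, adjusted p = 0.0196) fell. Mrgprb2, a receptor that triggers mast cell degranulation, fell by 2.10 (adjusted p = 0.0243; above background on 1 of 3 sgp130Fc arrays). The list median was 2.17 on IL6_KO replicate 2 and -0.81 to 0.25 on the other 7 arrays, and without that array the difference was -0.62 and still called.

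Of 15 lipid-associated macrophage genes 3 fell, among them Mmp12 (-1.61, adjusted p = 0.0467) and Ctsk (-1.37, adjusted p = 0.0385). Adjusted over the list alone 7 were lower (median -0.58, adjusted p = 5.29e-06; adjusted p = 0.615 with an estimated correlation). The pan-macrophage list was not called, with 0 of 20 passing, also adjusted over the list alone (median -0.24, adjusted p = 0.0753; adjusted p = 0.723 with an estimated correlation). It was called without IL6_KO replicate 3 (-0.32) or sgp130Fc replicate 3 (-0.34). Its median was -0.10 without IL6_KO replicate 2, -0.15 without sgp130Fc replicate 1 and -0.16 without sgp130Fc replicate 2. Adgre1 differed by -0.20 (adjusted p = 0.595), Itgax by -1.11 (adjusted p = 0.114), Ccl2 by -1.37 (adjusted p = 0.0906) and Tnf by -0.77 (adjusted p = 0.11). Without IL6_KO replicate 2 Ccl2 passed (-1.82). Of 23 chemokine genes the interferon-induced Cxcl10 fell (at least 1.86-fold, adjusted p = 0.00795) and the receptor Cxcr4 rose (1.36, adjusted p = 0.0174). Adjusted over the list alone 2 chemokine genes were higher and 8 lower (median -0.33, or -0.30 with dim genes at their bound, adjusted p = 0.0117; adjusted p = 0.479 with an estimated correlation). That call was lost with detection on all arrays.

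Vessel, blood and fat cell genes lay higher in sgp130Fc. All 16 endothelial genes had a positive difference, 4 rose, 12 did not pass, and 12 were higher when adjusted over the list alone (median 0.80, adjusted p = 3.72e-09). The endothelial list had adjusted p = 0.479 with an estimated correlation. Emcn, a sialomucin of capillaries and veins, rose from 8.95 ± 0.10 to 9.77 ± 0.05 (adjusted p = 0.0259), and Gpihbp1 rose by 1.46 (adjusted p = 0.0404). Of 5 erythroid genes 3 rose, among them Hbb-bt, 4.78-fold (adjusted p = 0.0103), and 5 were higher when adjusted over the list alone (median 1.82, adjusted p = 4.39e-06). The erythroid list had adjusted p = 0.479 with an estimated correlation. Of 9 smooth muscle genes Myh11 rose (1.17, adjusted p = 0.0342), and 2 were higher when adjusted over the list alone (median 0.57, adjusted p = 0.00183). That list had adjusted p = 0.479 with an estimated correlation.

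Lipogenesis genes were positive in 20 of 20 members, with 0 passing and 3 higher when adjusted over the list alone (median 0.66, adjusted p = 9.58e-06). These had adjusted p = 0.646 with an estimated correlation, and Fasn differed by 1.10 (adjusted p = 0.119). Adipocyte markers were positive in 19 of 20, with 0 passing and 1 higher when adjusted over the list alone (median 0.85, or 0.83 with dim genes at their bound, adjusted p = 2.49e-05). The adipocyte list had adjusted p = 0.615 with an estimated correlation. Pparg, the regulator of fat cell formation, differed by 0.81 and Pck1, an enzyme of glyceride synthesis, by 1.29 (adjusted p = 0.0584). Lipolysis genes had a median of 0.76 over 13 members, or 0.73 with dim genes at their bound (adjusted p = 0.00161; adjusted p = 0.653 with an estimated correlation). For 20 fatty acid oxidation genes it was 0.35 (adjusted p = 0.00233; adjusted p = 0.661 with an estimated correlation). In both 0 passed, also adjusted over the list alone. Of 13 adipokines Lcn2 rose, and 3 were higher when adjusted over the list alone (median 0.58, adjusted p = 0.0026; adjusted p = 0.615 with an estimated correlation). Without IL6_KO replicate 2 the medians were 0.27 for lipogenesis, 0.35 for adipocyte markers, 0.34 for lipolysis, 0.29 for adipokines and 0.17 for fatty acid oxidation, the last no longer called.

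In 4 further lists that lay lower in sgp130Fc 0 members passed, also adjusted over the list alone. Phagosome and lysosome genes had a median of -0.38 over 21 (adjusted p = 0.0134; adjusted p = 0.653 with an estimated correlation), and -0.16 and no call without IL6_KO replicate 2. Cell cycle genes had -0.25 over 19 (adjusted p = 0.00482; adjusted p = 0.670 with an estimated correlation), and -0.17 without background correction. Mesothelial genes were negative in 12 of 12 (median -0.48, or -0.43 with dim genes at their bound, adjusted p = 0.0108; adjusted p = 0.670 with an estimated correlation). Their call was lost without sgp130Fc replicate 1 (-0.33) and with detection on all arrays, and the median was -0.76 without sgp130Fc replicate 3, -0.25 without background correction and -0.72 with array weights. Ribosomal protein genes were negative in 18 of 19 (median -0.15, adjusted p = 0.0407; adjusted p = 0.653 with an estimated correlation). Their call was lost without IL6_KO replicate 1 (-0.15) or 2 (-0.09) or sgp130Fc replicate 1 (-0.15), with scaling to the 75th percentile (-0.07) and with the replicate block. The lysosomal protease gene Ctsl differed by -0.77, the thymidylate synthase gene Tyms by -0.80, Igfbp6 of the mesothelial list by -0.49 and the ribosomal Rplp0 by -0.26.

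Of 9 liver genes Apoa2 fell, 8 did not pass, and 7 were lower when adjusted over the list alone (median -2.51, adjusted p = 0.000139; adjusted p = 0.615 with an estimated correlation). The median was -1.57 without IL6_KO replicate 3, the array where these genes were brightest. Lep differed by 0.50, Adipoq by 0.43, Slc2a4 by 0.90 and Saa3 by 1.17, and these did not pass. Without IL6_KO replicate 2 Lep differed by 0.14, Adipoq by 0.03 and Slc2a4 by 0.50. Of 44 lists 19 were called, 10 higher and 9 lower, and 0 with an estimated correlation or with fry. The 9 other splits of these 6 arrays into 3 and 3 called 4 to 22 lists and 0 probes. The 179 probes passing (115 higher, 64 lower; 2517 at an unadjusted p under 0.05) became 43 and 495 without IL6_KO replicates 1 and 3, and 35, 26 and 24 without sgp130Fc replicates 1, 2 and 3. Prkag2, Depp1, Chil1, Ddit4, Ctse, Per2, Napepld and Mcm6 passed with each array left out, and the other 12 genes named from the extremes did not, at adjusted p up to 0.173. Of 15 further named genes that passed, Per1 did so with each array left out and 14 did not, at adjusted p up to 0.185. Of all 179 passing probes, 19 passed with each array left out.

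Gdpd3, Gbp2b and Timmdc1 fell in both genotypes against WT and Kansl1l rose in both. Independent lists would share 0.0106 lower and 0.00495 higher probes, and 0 probes were called in opposite directions. Because both comparisons use the same 2 WT arrays, part of this excess may come from the shared controls. The simulations did not count shared calls, so that was not tested. Over all probes the log2 differences correlated at r = 0.474, below the mean of 0.600 in simulations without any group difference, while their covariance was 0.0839 against a simulated 0.0394. Between sgp130Fc and IL6_KO these genes differed by -0.16 (Gdpd3, adjusted p = 0.657), 0.31 (Timmdc1, adjusted p = 0.406) and 0.35 (Kansl1l, adjusted p = 0.307). Gbp2b was above background on 0 IL6_KO arrays and 1 sgp130Fc array, so no difference between them can be given.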

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

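No test in this part was chosen after the results were seen. No passing probe changed sign under any alternative, and the deposited log2 values gave 35, 13 and 177 calls. For IL6_KO minus WT the 35 calls became 21 without background correction, 9 without a detection filter, 13 with detection on all arrays, 64 with an intensity trend, 268 with array weights, 5 with the compared groups alone, 12 with the replicate block and 6 to 778 with an array left out. For sgp130Fc minus WT the 13 became 8, 6, 5, 20 and 28 under the first 5 of these, 22 with an offset of 50, 5 with the replicate block and 3 to 21 with an array left out. For sgp130Fc minus IL6_KO the 179 became 107 without a filter, 1730 with array weights, 79 with the replicate block and 24 to 495 with an array left out. The cause was not tested, except that a filter changes how many probes are adjusted for and a left-out array changes the number of samples; a group left with 1 array is assumed to vary like the others. The array weights stopped before reaching their tolerance. Replicate numbers showed no clear pairing of the samples: 2 of 7 same-number pairs correlated above 0.1 after group means were removed, and 0 arrays did so best with their own number. So few pairs, tied to each other by the removed means, cannot exclude a pairing. A chip block was not run, since the files name no chips.

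The pan-macrophage shifts of 0.76 and 0.56 against WT lost their calls with an estimated correlation (adjusted p = 0.479 in both) and with fry (adjusted p = 0.0740 and 0.129). The shift of -0.24 between sgp130Fc and IL6_KO was called with array weights (-0.25) and with the mean of all probes (-0.38). With an array left out it ranged from -0.34 to -0.10 and was called without replicate 3 of either group. Against WT, sgp130Fc turned direction without WT replicate 1 for T and NK cell genes (0.035, range -0.90 to 0.04) and for cell cycle genes (-0.024, range -0.02 to 0.58). Of 4916 values of named genes 4337 kept their direction and call, 412 lost the call, 160 gained it and 7 turned, none of them passing: Saa3 in IL6_KO minus WT (array weights -0.21, arrays left out -0.76 to 1.14), Il6ra (-0.27 to 0.23) and Itgax (-0.52 to 0.059) in sgp130Fc minus WT with arrays left out, and in sgp130Fc minus IL6_KO Il6ra (array weights 0.0095) and Il6st (arrays left out -0.068 to 0.067); of 1029 values of other lists 872 kept both, 155 lost the call and 2 turned. Of 49 called results of other lists, detection on all arrays ended 11, no filter 5, scaling to the 75th percentile 4, the replicate block 2, array weights 1, the mean of all probes 1, and an estimated correlation or fry 49. Signal near background limits what can be seen: the detection limit lay at 4.94 to 5.12 on the log2 scale, so a fall from a level near it, such as that of Il6 in WT, cannot be measured.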

Other observations

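Of the tests below, those of a variant under the probe, of chromosome segments, of the adipocyte and macrophage pattern, of the time of day and of the reduced glucocorticoid and FOXO lists were chosen after the results were seen. The full glucocorticoid and FOXO lists and the splits for called lists were also prompted by results, and set before their own values were seen. Some members of the glucocorticoid and FOXO lists, however, also belong to lists tested before. Only the splits for probes and the test of donor DNA near Il6 were set before any result.

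Further gene groups lay apart between IL6_KO and WT. Mast cell and granulocyte genes were positive in 13 of 13 members, with 0 passing and 3 higher adjusted over the list alone (median 1.29, or 0.97 with dim genes at their bound, adjusted p = 0.0023). They had adjusted p = 0.653 with an estimated correlation, and lost the call without IL6_KO replicate 2 (0.33); Cpa3 differed by 1.93. Cell cycle genes were positive in 19 of 19, with 0 passing and 2 higher adjusted over the list alone (median 0.47, adjusted p = 1.54e-05; adjusted p = 0.615 with an estimated correlation). Their median was 0.24 without WT replicate 1 and 0.75 without WT replicate 2, and the topoisomerase Top2a differed by 1.00. Mesothelial genes, which mark the lining of abdominal organs, were positive in 12 of 12, with 0 passing, also adjusted over the list alone (median 0.59, adjusted p = 0.00494; adjusted p = 0.653 with an estimated correlation). The uroplakin Upk3b differed by 1.55, with levels of 8.56 and 5.89 on WT replicates 1 and 2. The list median was 0.96 without WT replicate 1, and 0.10 and no longer called without WT replicate 2. Oxidative phosphorylation genes were negative in 25 of 27, with 0 passing and 1 lower adjusted over the list alone (median -0.23, adjusted p = 0.0107; adjusted p = 0.646 with an estimated correlation). It was -0.13 without WT replicate 1 and -0.11, not called, without IL6_KO replicate 2. Of 9 brown and beige fat genes 0 passed and 5 were lower adjusted over the list alone (median -0.82, adjusted p = 0.0382; adjusted p = 0.682 with an estimated correlation). That call was lost without WT replicate 1 (-0.78) or IL6_KO replicate 2 (-0.49), and with no detection filter. Detection on all arrays ended the calls of the mesothelial and of the brown and beige fat list.

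Of 14 inflammatory cytokine genes Il1rn rose in IL6_KO, 13 did not pass, and 2 were higher adjusted over the list alone (median 0.36, or 0.33 with dim genes at their bound, adjusted p = 0.00858; adjusted p = 0.615 with an estimated correlation). The median was 0.24, not called, without WT replicate 2 and 0.21 without IL6_KO replicate 2. Il1rn blocks IL-1 signalling, and Il1b, not above background in WT, was at least 1.78-fold higher without passing (adjusted p = 0.241). Interferon-induced genes were positive in 18 of 22 between sgp130Fc and IL6_KO, with 0 passing, also adjusted over the list alone (median 0.38, adjusted p = 0.0141; adjusted p = 0.706 with an estimated correlation). Oas2, which senses viral RNA, differed by 1.13, and the call was lost without IL6_KO replicate 3 (0.20) or sgp130Fc replicate 2 (0.21). Inflammatory cytokine genes lay lower there, with 0 passing and 1 higher and 3 lower adjusted over the list alone (median -0.40, or -0.34 with dim genes at their bound, adjusted p = 0.0147; adjusted p = 0.615 with an estimated correlation). In both comparisons detection on all arrays ended that call.

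Genes called against WT crowd on 1 side of Il6 in IL6_KO and on chromosome 1 in sgp130Fc. DNA of the strain in which Il6 was targeted may lie beside it, since 5 of 178 genes there were called (one-sided Fisher's exact p = 0.000220, but p = 0.0656 for the 6 called between sgp130Fc and IL6_KO). For Napepld, Kcnh2 and Nos3 a variant under the probe alone is argued against by 4 of 4 further probes that moved the same way. Prkag2 and Abcb4 had no further tested probe, so for them a variant under the probe stays open. Against WT, 5 of the 12 called genes lie in a window of 400 gene places, which 0% of 1000 random draws matched, but Kansl1l among them also rose in IL6_KO (1.38). Without the genes called in both, 4 of 8 remain (Per2, Mcm6, Ctse and Chil1, 0.2% of draws), so a linked segment that differs in the sgp130Fc mice could account for these 4. Per2, however, also moved with other clock genes against IL6_KO, where 3 of 16 clock genes rose and 2 fell. The draws were not repeated without Per2, so whether a segment accounts for it stays open. Against IL6_KO the most crowded window held 10 called genes, which 20.2% of draws matched, and 2 of 6 further probes there moved the same way by at least 0.5, so a variant under the probe may account for part, as for Mcm6, whose other probes differed by -1.25 and -0.38. An effect of genotype or age on these genes stays open and untested.

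Adipocyte markers lay lower and macrophage markers higher in IL6_KO. Without IL6_KO replicate 2 the macrophage median was 0.59 in place of 0.76, which argues against that array alone for the macrophage part. The adipocyte median was -0.49 in place of -1.05 with the camera call kept (adjusted p = 3.98e-06), so how much of that part rests on the array stays open. On all arrays both lists lost their calls with an estimated correlation (camera adjusted p = 0.479 for macrophage and 0.615 for adipocyte markers). A lower share of adipocytes alone would raise the markers of every other cell type. Smooth muscle genes lay lower (median -1.23), which argues against it, although that call was lost with an estimated correlation (adjusted p = 0.479). A change in macrophage number or state with genotype or age may remain and was not tested.

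Ddit4, Per1 and Pdk4, which glucocorticoids induce, were among the genes that rose in sgp130Fc against IL6_KO. A list of 21 other glucocorticoid-responsive genes had a median of 0.54 (18 positive, camera p = 1.25e-07, p = 0.00755 with an estimated correlation). It was 0.54 again without Lpin1, named by the rule for named genes, and 3 genes shared with the FOXO list (16 of 17 positive, 95% bootstrap interval 0.41 to 0.72, p = 0.00506 with an estimated correlation). The bootstrap resampled genes and not arrays, so its interval does not measure the spread between samples. Dusp1, Mt1, Mt2 and Nfkbia, kept in the reduced list, also belong to the 44 lists tested before. Dusp1 and Mt2 were the 2 members that passed when limma p-values were adjusted over 9803 genes with 1 probe each (adjusted p = 0.0144 and 0.0493). Elsewhere passing means adjusted over all probes, where Pck1, also at 0.0493 over genes, did not pass. The camera p-values of the glucocorticoid list, and of the FOXO list below, were not adjusted over lists, unlike those of the 44 lists. For scale, the clock list had camera p = 0.0193 with an estimated correlation before that adjustment and 0.479 after it. A difference in glucocorticoid exposure may be involved, but the glucocorticoid list is not wholly independent of the results seen before. A list of 12 FOXO targets of fasting had a median of 0.34 (camera p = 0.0252, p = 0.0648 with an estimated correlation). Without the named Pck1 and the 3 shared genes it was 0.34, with a bootstrap interval over genes of -0.60 to 0.55 (6 of 8 positive, camera p = 0.113, p = 0.162 with an estimated correlation). Per the labels the mice had fasted for 5 h, with no difference between groups named. Whether fasting state differed all the same is left undecided by the FOXO list. Evening clock genes were positive in 6 of 6 and morning genes in 0 of 4, with medians 1.30 apart, but all of them belong to the clock list seen before, so this cannot tell whether the time of collection, not given in the labels, differed. These explanations, and a direct effect of genotype or age, stay open together.

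For sgp130Fc minus IL6_KO the 6 arrays allow 10 splits, too few for a share under 0.05. The real split gave 179 probes and the highest other 0, so 1 of the 10 splits gave as many. For called lists the real split gave 19 and the 9 others 4 to 22, so 2 of the 10 gave as many, and these list calls are not set apart from other groupings of the arrays. The split with 22 set IL6_KO replicates 1 and 2 with sgp130Fc replicate 3 against the rest.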
